A study of Mus musculus with 10 samples.

How the data were processed

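Total RNA from mouse FDB1 cells with the FI-Delta or the FI-Delta Y577F receptor mutant, grown with IL-3 (0 h) or kept without it for 72 h, was labelled with Cy5 and Cy3 by an indirect method and hybridised in pairs to 10 spotted oligonucleotide arrays. The deposited values are log2 ratios of the channels of each array, normalised by the authors. The log base and the direction are not stated by the labels. Base 2 was assumed because limma, which the submitters' processing notes name without version or settings, writes log2 ratios, and the direction is likely Cy5 over Cy3 for the same reason. The relative orientation was checked on arrays of opposite dye assignment, whose deposited ratios correlated negatively across features, with r of -0.52 at 72 h, -0.63 for the time arrays of Y577F cells, and -0.24 and -0.35 for those of FI-Delta cells. At 0 h the pairs of opposite dye had r of -0.09 and 0.04, which did not settle the orientation over all features. After turning, the medians of MHC class II genes (0.584, 0.765 and 0.722) and of secondary and tertiary granule genes (-0.451, -0.691 and -0.482) had the same sign on 0 h arrays 1, 2 and 3. Turning all signs would turn every direction reported here. Background correction and normalization method are not given in the sources used here. Array medians lay between -0.0162 and 0.00900 and standard deviations between 0.232 and 0.371. Signal intensities were not analysed here, so the depth of single spots is unknown, and the number of arrays limits the precision.

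Of 23040 spots, 1243 control spots were left out. Of 21797 probes kept, 16651 carried a single gene symbol, 137 several and 5009 none. Probes with the same single symbol were averaged (1050 genes had more than 1 probe), and every other probe was its own feature, which gave 20243 features, 15097 of them with a symbol. For 15973 single-gene probes the gene identifier was found in the reference table, and 0 symbols were changed. There were 0 missing values. No genome build was used and no position is reported. Some probes may detect several members of a gene family.

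The arrays that carried RNA of FI-Delta 0 h and 72 h cultures with number 2 in both dye assignments were averaged and entered as 1 hybridisation, which left 9. A linear model was fitted with limma 3.58.1 in R 4.3.3, with 3 coefficients for the 4 RNA groups and a dye term for each feature, 5 residual degrees of freedom and empirical Bayes moderation (6.34 prior degrees of freedom). From this fit, 5 comparisons were taken, namely 72 h over 0 h in each line, Y577F over FI-Delta at each time, and the difference between the lines in their 72 h change. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 20243 features within a comparison, and a feature was called at an adjusted p under 0.05. The dye term was called in 146 features. The p-values treat the arrays as independent although arrays share RNA extracts. The design text gives 2 biological replicates per line. Replicate numbers run from 1 to 4 in the labels. On arrays with Y577F RNA in Cy5 and FI-Delta RNA in Cy3 they are given to the opposite lines. Extracts were therefore read as cultures 1 and 2 of FI-Delta and 3 and 4 of Y577F in title order, which is used only in the replicate block.

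The named genes, the gene lists, the comparisons and the alternatives were fixed before the data were examined. Named genes are, for each comparison, the 12 largest positive and 12 largest negative changes among called features with a symbol and with the same sign on every direct array (for the difference between changes, called features), up to 4 called members of each gene list by size of change (the 2 largest as values where none was called), and Csf2rb and Csf2rb2, of which Csf2rb had no named feature. A few others, such as list members that went against their list, were chosen after their values were seen. The 26 lists were primary granule proteins, secondary and tertiary granule proteins, monocyte and macrophage markers, mast cell and basophil markers, erythroid and megakaryocyte markers, lymphoid markers, mitosis genes, DNA replication genes, ribosome biogenesis and Myc target genes, ribosomal proteins, STAT5 and cytokine feedback targets, ERK and immediate-early genes, FoxO and growth arrest genes, apoptosis regulators, cholesterol synthesis genes, glycolysis genes, oxidative phosphorylation genes, ATF4 and amino acid response genes, interferon-stimulated genes, MHC class II genes, lysosome genes, GM-CSF receptor pathway components, blood transcription factors, histones, proteasome subunits, and heat shock and unfolded protein genes. Members with several list memberships count in each. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 26 lists within a comparison. Members were counted both with adjustment over all features and adjusted over the list alone.

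Overlaps between comparisons were set against the count for independent lists. The correlation of the lines' changes used only the time arrays, which share no RNA, and no p is given because features are not replicates. Alternatives were no dye term, the dye swap as 2 arrays, arrays centred, arrays centred and scaled to the same spread, a replicate block with a coefficient for each of 8 RNA extracts and no dye term (few residual degrees of freedom are left), only the arrays that compare the groups directly, a robust variance model, array weights, each probe on its own, only features with a symbol, and each array left out in turn. The replicate block takes each extract as fixed, so variation between cultures does not enter its p-values. The alternative with only the direct arrays has no dye term and fits the spread anew in each comparison. The procedure was tested on simulated data with 20 draws of 20243 features. Of changes of 0.5 (log2), 68.9% to 86.8% were recovered, and of changes of 1 at least 99.6%. Between 5.4% and 6.6% of calls were false. The simulated noise was independent between arrays, without effects of shared extracts or cultures, so these rates need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.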

Results

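RNA abundance was compared within and between a pair of mouse FDB1 cell lines on 10 two-colour spotted oligonucleotide arrays. FDB1 is a myeloid progenitor line that needs IL-3 to grow. One line carried FI-Delta, an activated mutant of the common beta chain shared by the GM-CSF, IL-3 and IL-5 receptors. The other carried FI-Delta Y577F, the same receptor with a tyrosine replaced by phenylalanine (Y577F below). RNA was taken from cells growing with IL-3 (0 h) and from cells washed and kept without the factor for 72 h, which gives 4 RNA groups with 2 cultures each. The lines were compared directly on 3 arrays at 0 h and on 2 arrays at 72 h. The time points were compared directly on 3 arrays in FI-Delta cells, of which 2 were a dye swap of the same RNA, and on 2 arrays in Y577F cells. After averaging of that dye swap, 9 hybridisations entered the model, and 20243 features were tested, of which 15097 carried a gene symbol. Values below are log2 changes ± standard error of the model over all of these arrays. The small number of arrays limits the precision, and the median standard error was between 0.0870 and 0.112 in the 5 comparisons.

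The change over time in FI-Delta cells compares cells kept for 72 h without IL-3 with cells growing in it. No RNA came from cells kept with IL-3 for 72 h. Loss of the factor therefore cannot be told apart from washing and time in culture, in either line. Genes for neutrophil granule proteins rose, and MHC class II genes and several mast cell and basophil markers fell. Ltf, which encodes the granule protein lactoferrin, rose 5.45-fold (2.45 ± 0.23), and Mmp8, the neutrophil collagenase, rose 4.63-fold (2.21 ± 0.17). Each was higher on all 3 arrays that compared the time points directly, a condition for naming the largest changes and not separate support. The mast cell carboxypeptidase gene Cpa3 fell by 2.57 ± 0.10, a 5.96-fold drop, and Gzmb, which encodes the protease granzyme B, fell by 2.67 ± 0.12, a 6.36-fold drop. In all, 1051 features rose and 601 fell (limma, adjusted p under 0.05). Of these, 97 of those that rose and 48 of those that fell changed at least 2-fold.

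Of 18 secondary and tertiary granule genes measured in FI-Delta cells, 15 rose, none fell and 3 did not pass (17 and 0 adjusted over the list alone). Besides Ltf and Mmp8 they included Camp (1.75 ± 0.15), which encodes the antimicrobial peptide cathelicidin, Ngp (1.71 ± 0.14), and Fpr2 (1.60 ± 0.14), a receptor for formylated peptides. Their median was 1.14 and the set lay above the other genes (camera adjusted p = 2.9e-25, and adjusted p = 0.0061 with an estimated correlation). Among 11 primary granule genes, 5 rose and 1 fell (6 and 1 over the list alone), with the neutrophil elastase gene Elane at 0.71 ± 0.11. Hp (0.87 ± 0.13) was counted among those that rose, although its place in primary granules is uncertain. The member that fell was Srgn at -0.54, which encodes the granule proteoglycan serglycin, was picked for mention after its values were seen and lost its call without FI-Delta time array 2. The primary granule set passed camera (adjusted p = 0.0024) but not with the other form of the test (adjusted p = 0.28 with an estimated correlation). The lectin gene Fcnb, one of the secondary and tertiary granule genes, rose by 1.66 ± 0.09. Other genes with large increases were Stfa3 (1.96 ± 0.23), a stefin A gene whose probe may also detect its close paralogs, and Slc40a1 (1.70 ± 0.10), the iron exporter ferroportin. Cldn1, Capn3, Slfn1 and 1700054A03Rik rose by between 1.62 and 1.89.

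Monocyte and macrophage markers also rose in FI-Delta cells, with 14 of 30 higher and none lower (20 and 1 adjusted over the list alone). The lysosomal protease gene Ctss rose by 1.48 ± 0.10 and Mpeg1, which encodes a pore-forming protein of phagocytes, by 1.35 ± 0.12 (camera adjusted p = 1.2e-11, and adjusted p = 0.0061 with an estimated correlation). Without FI-Delta time array 3, 7 of these markers were higher. Of 39 lysosome genes, 16 rose and none fell (21 and 0 over the list alone), including Psap at 1.26 ± 0.13 (camera adjusted p = 1.1e-10, and adjusted p = 0.06 with an estimated correlation). Of 9 MHC class II genes, 7 fell and none rose (8 and 0 over the list alone), with H2-Aa at -1.78 ± 0.10, H2-Eb1 at -1.57 ± 0.13 and Cd74, the invariant chain, at -0.83 ± 0.11. Their median was -0.61 (camera adjusted p = 1.4e-10, and adjusted p = 0.009 with an estimated correlation). H2-Ea, outside that list, fell by 1.85 ± 0.15, and probes for H2 genes may detect related family members. Of 16 mast cell and basophil markers, 4 fell, with the receptor gene Fcer1a at -1.44 ± 0.21 and the transcription factor gene Gata2 at -1.08 ± 0.11 beside Cpa3 (camera adjusted p = 0.0054, and adjusted p = 0.082 with an estimated correlation). In the same list 1 marker rose, a call lost without 0 h array 1, 72 h array 1, FI-Delta time array 2 or 3, or Y577F time array 2.

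Genes for making ribosomes fell in FI-Delta cells, with 15 of 40 ribosome biogenesis and Myc target genes lower and 1 higher (25 and 2 adjusted over the list alone). Nop16 changed by -0.75 ± 0.13 and Apex1 by -0.75 ± 0.09, while Bop1, which also acts in ribosome assembly, rose by 0.73 ± 0.09 (camera adjusted p = 8.2e-12, and adjusted p = 0.0061 with an estimated correlation). Without FI-Delta time array 2 or 3, 8 of these genes were lower. None of 38 mitosis genes was called, and their median was 0.06, with Mki67 at 0.34 ± 0.12 (adjusted p = 0.117) and Ccna2 at 0.31 ± 0.11 (adjusted p = 0.12). Of 47 DNA replication genes, 5 fell, including Mcm3 at -0.53 ± 0.08 (camera adjusted p = 0.00013, and adjusted p = 0.16 with an estimated correlation). Of those 5, the count was 2 without 0 h array 1, 72 h array 2 or Y577F time array 1, and 1 without FI-Delta time array 3. Of 35 ERK and immediate-early genes, 11 rose, led by the transcription factor gene Egr1 at 1.41 ± 0.11 (camera adjusted p = 0.0022, and adjusted p = 0.16 with an estimated correlation). Besides Gzmb, large declines outside these lists were in Tmtc2 (-2.76 ± 0.12), the thrombin receptor gene F2r (-2.34 ± 0.11), Fam20a (-2.09 ± 0.16) and the integrin gene Itga2b (-1.99 ± 0.11). Rab27b, Akr1c13, Tnfsf11 and Spns2 changed by between -1.84 and -1.63. The count of 1652 features fell to 887 without array 3 of the FI-Delta time arrays, to 544 with a replicate block for each RNA extract and no dye term, and to 912 from the direct arrays alone. It was 3786 with array weights. Unadjusted p was under 0.05 for 3999 features.

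**Figure D1:**
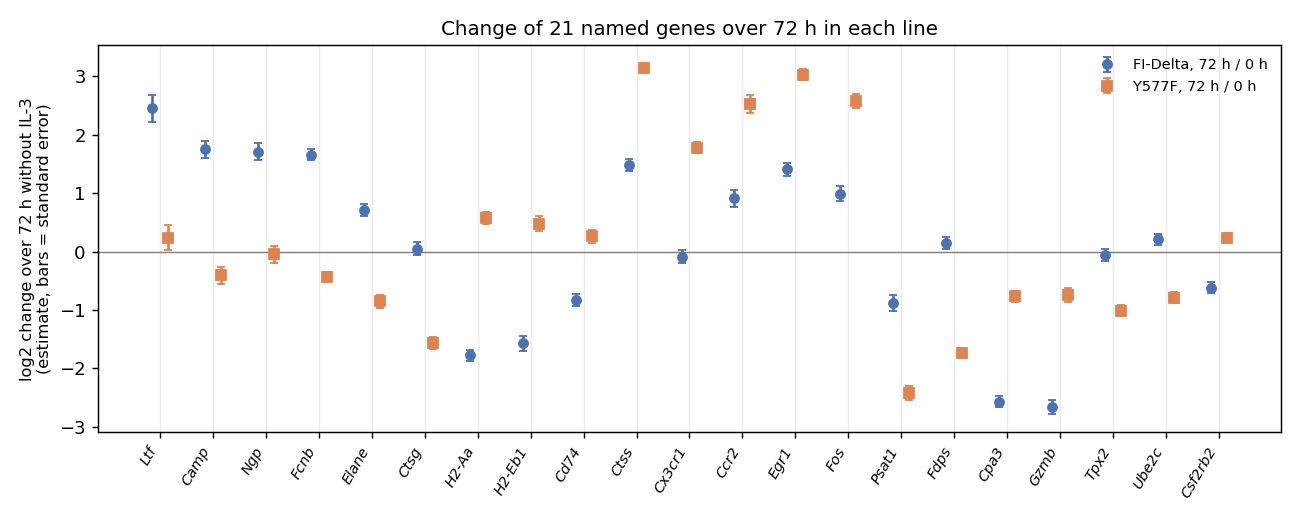
Log2 change over 72 h without IL-3 (vertical axis) of 21 named genes (horizontal axis) in FI-Delta cells (circles) and Y577F cells (squares); points are model estimates and bars are standard errors. Ltf, Camp, Ngp and Fcnb lay between 1.66 and 2.45 in FI-Delta cells and between -0.45 and 0.24 in Y577F cells, and Ctss, Egr1 and Fos rose in both lines and more in Y577F cells.

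In Y577F cells, loss of IL-3 was followed by a rise of monocyte, macrophage and lysosome genes and by a fall of genes for cell division. Ctss rose 8.84-fold (3.14 ± 0.09), Egr1 rose 8.17-fold (3.03 ± 0.10) and Clec7a, the macrophage beta-glucan receptor, rose 7.98-fold (3.00 ± 0.09). Psap, which encodes the precursor of the lysosomal saposins, rose 7.56-fold (2.92 ± 0.13). The cytokine gene Tnfsf11 fell by 2.62 ± 0.14, a 6.15-fold drop, and Psat1, an enzyme of serine synthesis, fell by 2.43 ± 0.12, a 5.37-fold drop. Each of these genes moved the same way on both direct arrays, which the rule for naming the largest changes required. In all, 1878 features rose and 1771 fell. Of these, 282 of those that rose and 92 of those that fell changed at least 2-fold.

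Of 30 monocyte and macrophage markers in Y577F cells, 22 rose and none fell (24 and 1 adjusted over the list alone). They included the chemokine receptor gene Ccr2 (2.53 ± 0.15), Mpeg1 (2.28 ± 0.11) and Cd68 (2.09 ± 0.09), with a list median of 0.93 (camera adjusted p = 1.7e-18, and adjusted p = 0.004 with an estimated correlation). Of 39 lysosome genes, 28 rose and none fell (30 and 0 over the list alone), with Lipa at 1.81 ± 0.09 and the cathepsin gene Ctsl at 1.64 ± 0.12 (camera adjusted p = 1.7e-18, and adjusted p = 0.021 with an estimated correlation). Of 35 ERK and immediate-early genes, 18 rose and 4 fell, with Fos at 2.57 ± 0.12 and Egr3 at 2.23 ± 0.10 (camera adjusted p = 1.2e-06, and adjusted p = 0.049 with an estimated correlation). The 4 that fell became 1 without Y577F time array 2, and 2 without 0 h array 1 or 2, FI-Delta time array 1 or 3, 72 h array 2 or Y577F time array 1. Of 9 MHC class II genes, 5 rose and none fell, led by H2-DMa at 1.15 ± 0.11 (camera adjusted p = 0.00024, and adjusted p = 0.049 with an estimated correlation). Without Y577F time array 1, 2 of the MHC class II genes were higher. The lectin gene Clec4n (2.64 ± 0.11), the macrophage elastase gene Mmp12 (2.63 ± 0.11) and the peptidase genes Enpep (2.63 ± 0.11) and Anpep (2.44 ± 0.12) also rose, as did Hpca (2.91 ± 0.10) and Naaa (2.50 ± 0.10).

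Secondary and tertiary granule genes did not move together in Y577F cells, where 3 rose, 2 fell and 13 of 18 did not pass (median 0.00, camera adjusted p = 0.54). The set was called by fry, with a mean of 0.18 (fry adjusted p = 0.036). Fpr2 rose by 2.37 ± 0.14, Csf3r, the G-CSF receptor, by 1.29 ± 0.10 and Mmp8 by 0.93 ± 0.16, and S100a9 changed by -0.67 ± 0.17, a call lost without Y577F time array 1. Of 11 primary granule genes, 9 fell and 2 rose, with the cathepsin G gene Ctsg at -1.57 ± 0.10 and the protease gene Ctsc at 0.99 ± 0.09 (camera adjusted p = 6e-05, and adjusted p = 0.13 with an estimated correlation). Of 16 mast cell and basophil markers, 5 fell and 2 rose, with Mcpt8 at -1.06 ± 0.12 (camera adjusted p = 0.0075, and adjusted p = 0.075 with an estimated correlation). The 2 that rose became 1 without Y577F time array 1.

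Of 38 mitosis genes in Y577F cells, 31 fell and none rose (33 and 0 adjusted over the list alone), with the spindle gene Tpx2 at -1.01 ± 0.10 and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, at -0.79 ± 0.09 (camera adjusted p = 1.9e-17, and adjusted p = 0.036 with an estimated correlation). Without Y577F time array 1, 16 mitosis genes were lower. Of 47 DNA replication genes, 29 fell and none rose (37 and 0 over the list alone), with Dut at -1.36 ± 0.13 and Mcm3 at -1.06 ± 0.08 (camera adjusted p = 2.8e-17, and adjusted p = 0.021 with an estimated correlation). Of 40 ribosome biogenesis and Myc target genes, 29 fell and 2 rose, with Nop56 at -1.46 ± 0.14 and the arginine methyltransferase gene Prmt1 at 1.13 ± 0.14 (camera adjusted p = 1.5e-15, and adjusted p = 0.005 with an estimated correlation). The 2 that rose became 1 without either Y577F time array. Of 33 ATF4 and amino acid response genes, 19 fell and 3 rose, with Shmt2 at -1.58 ± 0.09 beside Psat1 and the transcription factor gene Cebpb at 1.36 ± 0.09 (camera adjusted p = 2.1e-10, and adjusted p = 0.019 with an estimated correlation). Of 18 cholesterol synthesis genes, 11 fell and none rose, led by Fdps at -1.74 ± 0.09 and Idi1 at -1.22 ± 0.12 (camera adjusted p = 7.7e-10, and adjusted p = 0.053 with an estimated correlation). Without Y577F time array 2, 7 cholesterol synthesis genes fell and 1 ATF4 and amino acid response gene rose. Scd1, a fatty acid desaturase, changed by -2.23 ± 0.12, and the alpha globin gene Hba-a1 by -1.82 ± 0.08. Fam20a, Tmtc2, Sytl3, 4932438H23Rik, Akr1c12, F2r and Sapcd1 changed by between -2.60 and -1.61. The count of 3649 features fell to 1949 without array 1 of the Y577F time arrays, to 1721 with a replicate block and no dye term, and to 2224 from the direct arrays alone. Unadjusted p was under 0.05 for 5869 features.

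The changes of the lines overlapped. Tmtc2, F2r, Fam20a and Tnfsf11 were among the 12 largest declines in each line. In both lines, 657 features rose and 382 fell, against 97.5 and 52.6 if the lists were independent. Opposite calls were made for 27 features that rose in FI-Delta and fell in Y577F cells, among them Elane (0.71 ± 0.11 and -0.85 ± 0.11) and Serpinb1a (0.63 ± 0.09 and -1.37 ± 0.09). The reverse held for 14 features, among them H2-Aa (-1.78 ± 0.10 and 0.58 ± 0.10), whose call in Y577F cells was lost without array 1 of the Y577F time arrays. Estimates of both changes draw on shared arrays, which gives them a correlation of 0.37 without any effect. From the direct arrays, which share no RNA, 342 features rose and 180 fell in both lines, against 38.0 and 14.5 if independent. Across the 20243 features, which are not independent replicates, the direct arrays of the lines correlated with r = 0.489 and a Spearman rho of 0.348. Without array 2 of the Y577F time arrays r was 0.352, and single pairs of cultures gave r between 0.211 and 0.484.

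With IL-3 present at 0 h, Y577F cells had more MHC class II RNA and less granule protein RNA than FI-Delta cells, which shows how the lines differed before the factor was removed. The chemokine gene Cxcl2 was 3.29-fold higher (1.72 ± 0.18) and the MHC class II gene H2-Ab1 2.47-fold higher (1.31 ± 0.08) in Y577F cells. The granule genes Ngp (-1.83 ± 0.12, a 3.54-fold difference), Camp (-1.78 ± 0.13) and Elane (-1.60 ± 0.10) were lower. All 3 direct arrays gave the same sign for each, a condition for naming the largest changes and so not separate support. In all, 189 features were higher and 98 lower in Y577F cells. Of these, 9 of the higher and 15 of the lower features differed at least 2-fold. The excess of higher features was not stable, with 29 higher and 28 lower without 0 h array 1, and 9 higher and 13 lower with a replicate block and no dye term. Array 1 had little correlation across features with arrays 2 and 3 of the opposite dye assignment (r = 0.09 and -0.04 after turning). Arrays 2 and 3, which share the dye assignment and, by their titles, the RNA with number 4, correlated with r = 0.36. In the reading used for the replicate block, arrays 1 and 2 also share RNA, of FI-Delta culture 1, but had r = 0.09. Shared RNA is thus not shown to be the source of the higher correlation.

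Of 9 MHC class II genes, 7 were higher at 0 h and none lower (9 and 0 adjusted over the list alone), with H2-Eb1 at 1.24 ± 0.11 (median 0.62, camera adjusted p = 8.7e-20, and adjusted p = 0.007 with an estimated correlation). Of 18 secondary and tertiary granule genes, 10 were lower and 1 higher (12 and 1 over the list alone), with Fcnb at -1.49 ± 0.08 (camera adjusted p = 4.2e-16, and adjusted p = 0.014 with an estimated correlation). The member that was higher, Fpr2 (0.69 ± 0.12), lost its call without 0 h array 1, 2 or 3 or Y577F time array 2. Of 11 primary granule genes, 5 were lower and none higher (8 lower and 3 higher over the list alone), with the proteinase 3 gene Prtn3 at -1.38 ± 0.12 (camera adjusted p = 2.3e-07, and adjusted p = 0.11 with an estimated correlation). Of 33 ATF4 and amino acid response genes, 9 were higher and none lower (18 and 0 over the list alone), including Atf4 itself at 0.56 ± 0.08 (camera adjusted p = 3.4e-13, and adjusted p = 0.014 with an estimated correlation). Of 22 STAT5 and cytokine feedback targets, 6 were higher, led by the signalling inhibitor gene Socs1 at 0.82 ± 0.14 (camera adjusted p = 1.6e-06, and adjusted p = 0.048 with an estimated correlation). Of 30 monocyte and macrophage markers, 3 were higher, including Ctss at 0.56 ± 0.08 (camera adjusted p = 2e-04, and adjusted p = 0.04 with an estimated correlation). No mitosis gene was called at 0 h by limma (median -0.07, camera adjusted p = 0.0065, and adjusted p = 0.41 with an estimated correlation), and the camera call was lost without 0 h array 2 (adjusted p = 0.128) or Y577F time array 2 (adjusted p = 0.059). Without 0 h array 1, 4 MHC class II genes, 1 ATF4 and amino acid response gene and 2 STAT5 and cytokine feedback targets were higher, and the 3 monocyte and macrophage calls were lost. The ATF4 count was 2 without 0 h array 3 and 5 without 0 h array 2 or 72 h array 1, and the STAT5 count was 3 without 0 h array 3.

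Other genes higher at 0 h were Akr1c12 (1.37 ± 0.11), the chemokine gene Ccl17 (1.16 ± 0.13), Scd1 (1.11 ± 0.11), Mst1 (1.10 ± 0.12) and Gpr34 (0.93 ± 0.08). Stfa1 (-1.49 ± 0.17), the adhesion molecule genes Ceacam1 (-1.38 ± 0.09) and Ceacam2 (-1.26 ± 0.09), S100a9 (-1.22 ± 0.15), Ms4a3 (-1.11 ± 0.09) and Pglyrp1 (-1.09 ± 0.08) were lower. Probes for Ceacam, Akr1c and stefin A genes may detect paralogs. Fcer1a (1.14 ± 0.18), Ctla2a (0.98 ± 0.14), Ccl4 (0.94 ± 0.16), Akr1c13 (0.93 ± 0.13) and Ltf (-1.27 ± 0.20) passed the test, but not without array 1 of the 0 h arrays. The same held for Socs3, Ctss and H2-Aa. The 287 calls fell to 57, 151 and 164 without 0 h arrays 1, 2 and 3 and to 171 without array 1 of the 72 h arrays. The count was 22 with a replicate block and no dye term, 46 from the direct arrays alone and 445 with array weights. Unadjusted p was under 0.05 for 2453 features.

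**Figure D2:**
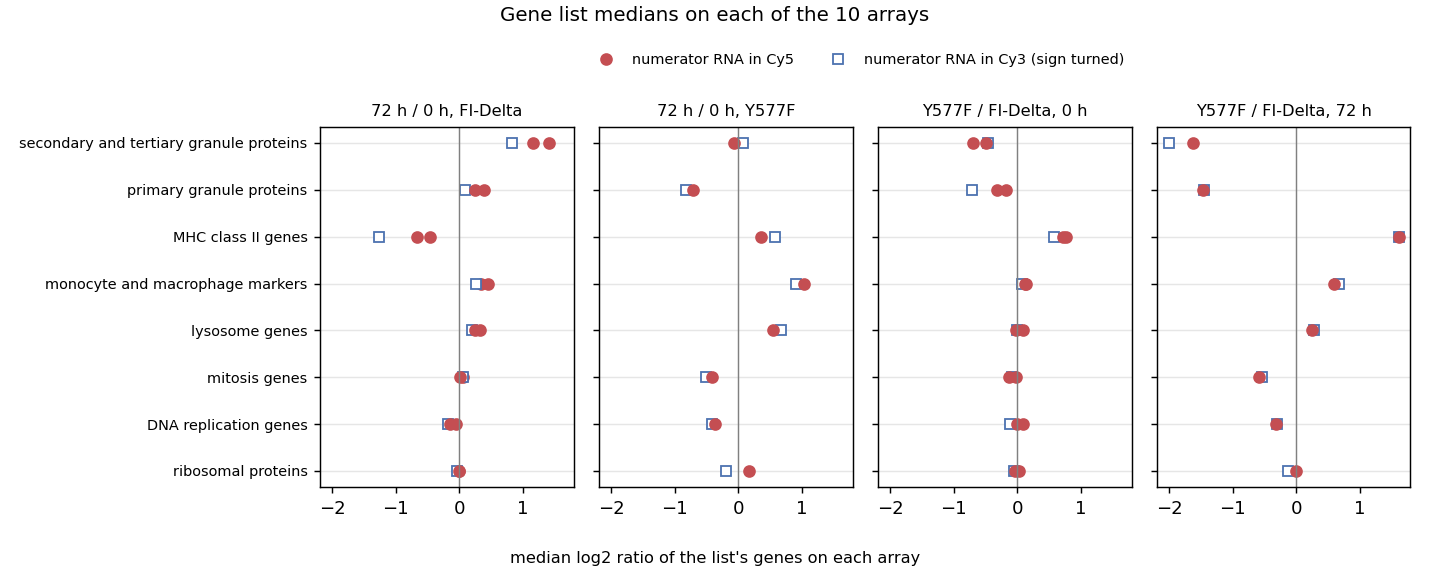
Median log2 ratio (horizontal axis) of 8 gene lists (vertical axis) on each of the 10 arrays, turned so that positive values mean higher at 72 h or higher in Y577F cells; filled circles have the numerator RNA in Cy5 and open squares have it in Cy3. At 72 h, MHC class II medians were at least 1.62 on both arrays and secondary and tertiary granule medians were -1.63 or lower, with opposite dye assignments.

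After 72 h without IL-3, the lines were further apart. Y577F cells had 9.77-fold more H2-Eb1 RNA (3.29 ± 0.13) and 10.2-fold more RNA of Ccl17, a chemokine of dendritic cells and macrophages (3.35 ± 0.15). Camp was 15.3-fold lower (-3.94 ± 0.15), Fcnb lower (-3.59 ± 0.09) and Elane 8.93-fold lower (-3.16 ± 0.11). Both direct arrays gave the same sign for each of these genes, which the rule for naming the largest changes required. In all, 1304 features were higher and 1305 lower in Y577F cells. Of these, 173 of the higher and 121 of the lower features differed at least 2-fold.

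All 9 MHC class II genes were higher in Y577F cells at 72 h, with H2-Aa at 3.03 ± 0.10, H2-Ab1 at 2.98 ± 0.09 and a list median of 1.57 (camera adjusted p = 2.3e-19, and adjusted p = 0.0038 with an estimated correlation). Of 30 monocyte and macrophage markers, 19 were higher and none lower (19 and 1 adjusted over the list alone), with Ctss at 2.22 ± 0.09 and the fractalkine receptor gene Cx3cr1 at 1.93 ± 0.10 (camera adjusted p = 9.9e-15, and adjusted p = 0.0038 with an estimated correlation). Of 39 lysosome genes, 19 were higher and 2 lower (24 and 3 over the list alone), with Lipa at 1.30 ± 0.09 and the sulfatase gene Arsb, which was lower, at -1.08 (camera adjusted p = 3.3e-09, and adjusted p = 0.046 with an estimated correlation). Without 72 h array 2, 12 lysosome genes were higher, and the 2 that were lower became 1 without either 72 h array. Of 35 ERK and immediate-early genes, 15 were higher and none lower, with Egr1 at 1.78 ± 0.10 and Egr3 at 1.69 ± 0.10 (camera adjusted p = 5.7e-07, and adjusted p = 0.042 with an estimated correlation). Mmp12 (2.83 ± 0.11), Gzmb (2.79 ± 0.12), Rassf4 (2.67 ± 0.13) and Adgre4 (2.47 ± 0.16), a receptor gene of macrophages, were also higher. Among 16 mast cell and basophil markers 4 were higher and 2 lower (camera adjusted p = 0.27, fry adjusted p = 0.0014). Fcer1a was at 2.32 ± 0.20, Cpa3 at 2.29 ± 0.10 and the histidine decarboxylase gene Hdc at -1.25 ± 0.08.

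Of 18 secondary and tertiary granule genes, 13 were lower in Y577F cells at 72 h and 2 higher (14 and 2 adjusted over the list alone), with Ngp at -3.59 ± 0.14 and Ltf at -3.48 ± 0.22. The receptor genes Fpr2 (1.46 ± 0.14) and Csf3r (0.36 ± 0.10) were higher, and the set lay below the other genes (camera adjusted p = 1.1e-17, and adjusted p = 0.011 with an estimated correlation). The Csf3r call was lost without either 72 h array, FI-Delta time array 1 or 3, or Y577F time array 2. Of 11 primary granule genes, 7 were lower and 1, Ctsc, higher (0.89 ± 0.09), with Prtn3 at -2.86 ± 0.13 (camera adjusted p = 7.4e-09, and adjusted p = 0.047 with an estimated correlation). Stfa1 (-3.79 ± 0.19), Stfa3 (-3.20 ± 0.22) and Stfa2 (-2.54 ± 0.18), whose probes may detect one another's RNA, and S100a9 (-2.86 ± 0.17), 1700054A03Rik (-2.72 ± 0.11) and Pglyrp1 (-2.60 ± 0.09) were lower.

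Of 38 mitosis genes, 32 were lower in Y577F cells at 72 h and none higher (34 and 0 adjusted over the list alone), with Ube2c at -1.14 ± 0.09 and the spindle midzone gene Prc1 at -1.03 ± 0.09 (median -0.62, camera adjusted p = 6e-24, and adjusted p = 0.026 with an estimated correlation). Of 47 DNA replication genes, 23 were lower (28 lower and 1 higher over the list alone), with the ribonucleotide reductase gene Rrm2 at -1.02 ± 0.16 (camera adjusted p = 9e-12, and adjusted p = 0.036 with an estimated correlation). Without 72 h array 2, 9 DNA replication genes were lower. Of 40 ribosome biogenesis and Myc target genes, 10 were lower and Prmt1 was higher (1.06 ± 0.14), with a list median of -0.18 (camera adjusted p = 3e-05, and adjusted p = 0.034 with an estimated correlation). Of those 10, the count was 5 without 72 h array 1 and 2 without 72 h array 2. Of 18 cholesterol synthesis genes, 6 were lower, led by Fdps at -1.92 ± 0.09 (camera adjusted p = 1.5e-06, and adjusted p = 0.086 with an estimated correlation). The 2609 calls fell to 1421 and 1403 without array 1 and array 2 of the 72 h arrays, to 1060 with a replicate block and no dye term, and to 1018 from the direct arrays alone. They were 5537 with array weights. Of the 287 features called at 0 h, 206 were called in the same direction at 72 h and 9 in the opposite one. These 206 held 123 higher and 83 lower in Y577F cells, against 12.2 and 6.3 for independent lists. Estimates at the 2 times have a correlation of 0.27 without any effect because they share arrays.

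The test of the difference between the lines in their 72 h change asks where the change over 72 h without IL-3 itself differed. H2-Aa fell in FI-Delta cells (-1.78 ± 0.10) and rose in Y577F cells (0.58 ± 0.10, a call lost without Y577F time array 1), a difference of 2.36 ± 0.12 (5.12-fold). Ltf, Camp and Fcnb rose in FI-Delta cells and did not rise in Y577F cells, with differences of -2.21 ± 0.26, -2.16 ± 0.17 and -2.10 ± 0.10. Fdps, the farnesyl diphosphate synthase gene, fell in Y577F cells (-1.74 ± 0.09) and was at 0.15 ± 0.10 in FI-Delta cells, a difference of -1.89 ± 0.11. The integrin gene Itgax rose in Y577F cells (2.24 ± 0.14) and was at 0.36 ± 0.15 in FI-Delta cells, a difference of 1.88 ± 0.16. In all, the change was larger in Y577F cells for 877 features and smaller for 994 (limma, adjusted p under 0.05), where larger means more positive. This balance was not stable, with 239 larger and 201 smaller with a replicate block and no dye term, 133 and 77 from the time arrays alone, and 462 and 449 without 72 h array 2.

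**Figure D3:**
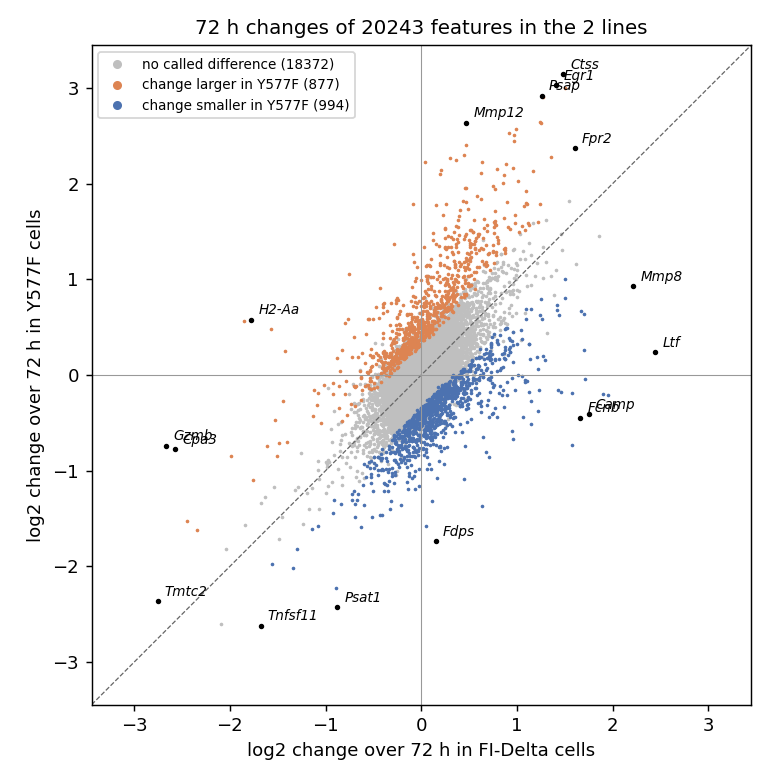
Log2 change over 72 h in FI-Delta cells (horizontal axis) and in Y577F cells (vertical axis) of 20243 features, 1 point each; the dashed line marks equal change. The change was more positive in Y577F cells for 877 features (orange) and more negative for 994 (blue), and 18372 features (grey) had no called difference; black points are named genes.

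Of 9 MHC class II genes, 8 had a more positive change in Y577F cells (8 adjusted over the list alone), including Cd74 at 1.09 ± 0.12 (median 1.03, camera adjusted p = 1.5e-14, and adjusted p = 0.0078 with an estimated correlation). Of 30 monocyte and macrophage markers, 14 had a more positive change and none a more negative one, with Cx3cr1 at 1.87 ± 0.12 and Ctss at 1.66 ± 0.11 (camera adjusted p = 6.6e-11, and adjusted p = 0.0078 with an estimated correlation). Of 39 lysosome genes, 16 had a more positive and 1 a more negative change, with Psap at 1.66 ± 0.15 (camera adjusted p = 1.4e-09, and adjusted p = 0.053 with an estimated correlation). The 1 more negative lysosome call was lost without 0 h array 1 or 2, either 72 h array or Y577F time array 1. Of 35 ERK and immediate-early genes, 12 had a more positive change, with Egr1 at 1.62 ± 0.12 and Fos at 1.58 ± 0.14 (camera adjusted p = 2.9e-05, and adjusted p = 0.062 with an estimated correlation). H2-Ea (2.41 ± 0.16), Ccl17 (2.18 ± 0.17), Mmp12 (2.16 ± 0.12), H2-Eb1 (2.05 ± 0.15), Adgre4 (1.97 ± 0.18), Dysf (1.93 ± 0.14), Gzmb (1.93 ± 0.14), Rassf4 (1.93 ± 0.15) and Ms4a6b (1.91 ± 0.14) had the other largest positive differences.

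Of 18 secondary and tertiary granule genes, 13 had a more negative change in Y577F cells and 2, Fpr2 (0.77 ± 0.16) and Csf3r (0.53 ± 0.11), a more positive one (median -1.13, camera adjusted p = 4.3e-14, and adjusted p = 0.019 with an estimated correlation). The calls of Fpr2 and Csf3r were lost without 72 h array 2. Of 11 primary granule genes, 7 had a more negative change and Ctsc a more positive one (0.62 ± 0.11), with Ctsg at -1.62 ± 0.12 (camera adjusted p = 3.2e-08, and adjusted p = 0.061 with an estimated correlation). Of 38 mitosis genes, 26 had a more negative change in Y577F cells and none a more positive one (33 and 0 adjusted over the list alone), with Tpx2 at -0.95 ± 0.11 (median -0.53, camera adjusted p = 6.7e-21, and adjusted p = 0.028 with an estimated correlation). Of 47 DNA replication genes, 18 had a more negative change (camera adjusted p = 4.1e-10, and adjusted p = 0.049 with an estimated correlation). Of 33 ATF4 and amino acid response genes, 17 had a more negative change and Cebpb a more positive one (0.68), with Psat1 at -1.54 ± 0.14 and Atf4 at -1.14 ± 0.10 (camera adjusted p = 3.2e-09, and adjusted p = 0.019 with an estimated correlation). Of 18 cholesterol synthesis genes, 7 had a more negative change (camera adjusted p = 8.6e-09, and adjusted p = 0.061 with an estimated correlation). Among 40 ribosome biogenesis and Myc target genes, 10 had a more negative change (camera adjusted p = 4.4e-05, and adjusted p = 0.031 with an estimated correlation). Without 72 h array 2, 7 DNA replication, 11 ATF4 and amino acid response and 5 ribosome biogenesis genes had a more negative change, and the last count was 6 without 0 h array 1, 72 h array 1 or Y577F time array 1. Stfa1 (-2.30 ± 0.22), Stfa3 (-2.17 ± 0.25), 1700054A03Rik (-2.10 ± 0.13), Serpinb1a (-2.00 ± 0.10), Stfa2 (-1.76 ± 0.21), Ngp (-1.76 ± 0.16) and S100a9 (-1.63 ± 0.19) had large negative differences. The 1871 calls fell to 951 without array 1 of the 0 h arrays, to 911 without array 2 of the 72 h arrays, to 440 with a replicate block and no dye term, and to 210 from the time arrays alone, where S100a9 was no longer called. Unadjusted p was under 0.05 for 4754 features.

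The receptor's own subunits and targets were read for both lines. Csf2rb2, which encodes an IL-3-specific beta chain and is the relative of the mutated chain that had a named probe, fell in FI-Delta cells (-0.62 ± 0.09) and was at 0.23 ± 0.09 in Y577F cells (adjusted p = 0.111), a difference of 0.85 ± 0.10. Csf2rb2 was higher in Y577F cells at 0 h (0.48 ± 0.08, a call lost without 0 h array 1, 2 or 3) and at 72 h (1.33 ± 0.09). The labels do not say whether its probe detects the introduced receptor. Csf2ra, the alpha chain of the GM-CSF receptor, rose in FI-Delta (0.98 ± 0.10) and Y577F cells (1.59 ± 0.10). Of 37 GM-CSF receptor pathway components, 4 rose and 3 fell in FI-Delta cells (camera adjusted p = 0.17). In Y577F cells, 13 rose and 3 fell (camera adjusted p = 0.00014, and adjusted p = 0.17 with an estimated correlation). Without FI-Delta time array 3, 1 rose and 1 fell in FI-Delta cells, and without Y577F time array 1, 6 rose in Y577F cells. The kinase gene Fgr rose by 0.51 ± 0.09 in FI-Delta cells, a call lost without array 2 or array 3 of the FI-Delta time arrays, and by 1.38 ± 0.09 in Y577F cells. Of 22 STAT5 and cytokine feedback targets, 10 were higher in Y577F cells at 72 h and none lower, with the prostaglandin receptor gene Ptger4 at 1.68 ± 0.10 and Socs3 at 0.99 ± 0.09 (camera adjusted p = 9.9e-07, and adjusted p = 0.036 with an estimated correlation). Socs1 fell in both lines, by 0.87 ± 0.16 in FI-Delta and by 0.98 ± 0.15 in Y577F cells, with a difference of -0.11 ± 0.17.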

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

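The tests of the MHC class II and granule pattern and of the mitosis pattern were chosen after the results were seen, and those of the dye swap pair were written before, except the comparison of that pair with the other FI-Delta pairs after removal of the dye term. Every result in this part was picked out because the 72 h change differed between the lines in a test of the difference itself, apart from the dye swap pair. The change was more positive in Y577F cells for 877 features and more negative for 994. Among the 24 genes with the largest change named for FI-Delta cells 19 had a called difference, and among the 24 for Y577F cells 21 did. Over all features, 1871 of 20243 had one. The named genes were picked for an extreme change in a line, which is itself part of the difference, so that choice favours high counts. Each RNA group holds only 2 cultures, too few to count results over other splits of the samples.

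MHC class II genes were higher and granule genes lower in Y577F than in FI-Delta cells at 72 h, and their changes differed between the lines, with median differences of 1.03 for MHC class II, -1.13 for secondary and tertiary granule genes and -1.08 for primary granule genes. The primary granule difference did not pass camera with an estimated correlation (camera adjusted p = 0.061). A dye bias would turn the sign between arrays of opposite dye. The MHC class II median was 1.62 or higher on both arrays at 72 h. The secondary and tertiary granule median was -1.63 on the array nearer to 0, so neither turned with the dye. The lists were picked from a fit that used these arrays with a dye term. The same sign was therefore likely beforehand and is no separate test of dye bias. For MHC class II the lowest 72 h array median lay 0.85 above the highest 0 h array median. For secondary and tertiary granule genes the distance was -0.93, so both differences were larger at 72 h. The lists were picked by the difference of the changes, which is the 72 h line difference minus the 0 h line difference. That choice made the 0 h difference carried along unlikely to fit as the whole cause, and these values are no separate test of it. Cross-hybridisation among H2 genes is argued against as the whole cause by Cd74 (1.46) and Ciita (0.70, a call lost without 72 h array 1), which share no such sequence and were higher at 72 h. The receptor mutation may underlie the pattern, but each mutant is present in a single line, so other differences between the lines were not tested and stay open.

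Mitosis genes were lower in Y577F cells at 72 h, and their median difference in change was -0.53. With arrays centred and scaled, 31 were lower instead of 32, so the count did not rest on that step. The spread of the 72 h arrays was already close, with median absolute deviations of 0.161 and 0.187. Scaling could therefore change little, and this is no test of other effects of normalization. The list median was -0.54 on the array nearer to 0 of the pair with opposite dye, so it did not turn with the dye. This list too was picked from the fit with a dye term, so the value is no separate test of dye bias. A lower share of dividing Y577F cells may account for this, but cell counts were not analysed here and the line difference stays open.

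The dye swap arrays of the same FI-Delta RNA correlated across features with r = 0.24, lower than arrays of different FI-Delta cultures in the same (r = 0.54) or the opposite dye assignment (r = 0.35). With the dye term estimated from the other arrays removed, r of the swap pair rose to 0.40, which is consistent with dye bias of single features as part of the cause. With the dye term removed in the same way, arrays 1 and 3 had r = 0.48 and arrays 2 and 3 r = 0.56, but array 3, unlike the difference of the swap arrays, entered the estimate of the dye term, so these values are not fully alike. The residual spread on the pair was at most 1.09 times the median of the arrays, which argues against a noisier array. Whether anything else lowers the correlation stays open.

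Other gene lists had median differences in the 72 h change of -0.51 for ATF4 and amino acid response genes, -0.28 for DNA replication genes, -0.26 for cholesterol synthesis genes, -0.21 for histones, -0.19 for proteasome subunits and -0.19 for ribosome biogenesis and Myc target genes. The camera call was lost for histones without 0 h array 1 (adjusted p = 0.0664), 72 h array 1 (0.0814), FI-Delta time array 2 (0.104) or Y577F time array 2 (0.0528), and for proteasome subunits without 72 h array 2 (0.0784). Positive median differences were 0.15 for STAT5 and cytokine feedback targets, 0.16 for ERK and immediate-early genes, 0.19 for GM-CSF receptor pathway components, 0.27 for interferon-stimulated genes, 0.29 for lysosome genes and 0.40 for monocyte and macrophage markers. With an estimated correlation, 7 of the 16 lists kept their call, namely mitosis, DNA replication, MHC class II, secondary and tertiary granule, monocyte and macrophage, ATF4 and ribosome biogenesis. Named genes with a more positive change in Y577F cells were H2-Ea (2.41), H2-Aa (2.36), Ccl17 (2.18), Mmp12 (2.16), H2-Eb1 (2.05), Adgre4 (1.97), Dysf (1.93), Gzmb (1.93), Rassf4 (1.93), Ms4a6b (1.91), Itgax (1.88) and Cx3cr1 (1.87). Named genes with a more negative change were Stfa1 (-2.30), Ltf (-2.21), Stfa3 (-2.17), Camp (-2.16), Fcnb (-2.10), 1700054A03Rik (-2.10), Serpinb1a (-2.00), Fdps (-1.89), Stfa2 (-1.76), Ngp (-1.76), S100a9 (-1.63) and Ctsg (-1.62).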

How the results depend on the processing

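All alternatives in this part were chosen before the data were examined. Counts of called features in the 5 comparisons (FI-Delta over time, Y577F over time, lines at 0 h, lines at 72 h, difference of changes) stayed within 1.5 times their value with no dye term, the dye swap as 2 arrays, arrays centred or also scaled, a robust variance model, each probe on its own and only features with a symbol. The missing-value alternative had nothing to act on, with 0 missing values. With array weights the counts were 3786 in FI-Delta cells over time, 445 between the lines at 0 h and 5537 at 72 h, and the cause was not tested, beyond the weight of 5.49 given to array 1 at 72 h. With only the direct arrays the counts were 912, 2224, 46, 1018 and 210. This setting leaves fewer arrays and few residual degrees of freedom, drops the dye term and fits the spread anew in each comparison. Which of these lowered the counts was not tested. At 0 h the direct arrays are not balanced for dye, so a dye bias stays in that count. With the replicate block, which also drops the dye term and leaves 2 residual degrees of freedom, they were 544, 1721, 22, 1060 and 440 (1489, 3086, 234, 2096 and 1600 with no dye term alone), of which 541, 1714, 22, 1053 and 435 were calls also made without it. Because the block takes each extract as fixed, its error is only the spread between arrays. Its counts are therefore not calls that hold over variation between cultures. Replicate numbers only share a number between times. The cultures' deviations at 0 and 72 h correlated with r = 0.71 in FI-Delta and 0.69 in Y577F cells, where the array layout alone gives 0.68 for each. Leaving out each array in turn, which removes data, gave 887 to 1953 calls in FI-Delta cells over time, 1949 to 3627 in Y577F cells over time, 57 to 299 between the lines at 0 h, 1403 to 2629 at 72 h and 911 to 1861 for the difference. The lowest counts came without FI-Delta time array 3, Y577F time array 1, 0 h array 1, 72 h array 2 and 72 h array 2. The correlation of the lines' changes ranged from 0.352 without Y577F time array 2 to 0.535. With an estimated correlation, 4, 8, 5, 11 and 7 of the 26 lists passed camera instead of 12, 19, 11, 18 and 16, and fry called 13, 22, 8, 19 and 19. With arrays left out in turn the ranges were 12 to 14, 16 to 19, 9 to 14, 16 to 18 and 15 to 17 lists. Of 469 calls of named genes, 112 were lost with the replicate block, 127 with the direct arrays alone, 8 to 56 with an array left out (56 without 0 h array 1), and at most 20 under any other setting. A single named gene changed direction: Atp5md rose by 0.55 in Y577F cells as the mean of 2 probes that disagree in sign, and was at -0.017 (adjusted p = 0.952) for a probe on its own, because averaging joins both. Signal over background was not analysed here, and no feature was left out for weak signal. The ratios of 506 empty or buffer spots had standard deviations of 0.233 to 0.401 on single arrays. Those of the probes were 0.232 to 0.371. Spots without a probe thus spread about as widely as the probes, and how many features lie near background is unknown.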

Other observations

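Interferon-stimulated genes were higher in Y577F cells at 72 h, with 19 of 35 called higher (22 adjusted over the list alone), including Trim30a (1.01 ± 0.09) and the transcription factor gene Irf7 (0.96 ± 0.16) (camera adjusted p = 2.2e-10, and adjusted p = 0.042 with an estimated correlation). Without 72 h array 1, 10 were higher. In the same list 1 gene was lower, a call lost without either 72 h array, 0 h array 2 or 3, Y577F time array 1 or FI-Delta time array 3. In FI-Delta cells over time the set was not called (camera adjusted p = 0.94), with Ifitm1 at -0.92 ± 0.10. Of 38 apoptosis regulators, 8 rose and 3 fell in FI-Delta cells (camera adjusted p = 0.1, fry adjusted p = 0.03). The 8 became 4 without 0 h array 1, 72 h array 2 or Y577F time array 1, and 5 without FI-Delta time array 2 or 3. In Y577F cells 10 rose and 5 fell, with 2 lower without Y577F time array 1, and the set was higher (camera adjusted p = 0.035, and adjusted p = 0.3 with an estimated correlation), a call lost without Y577F time array 1 (adjusted p = 0.0742) or 2 (adjusted p = 0.0735). Bcl2a1a and Bcl2a1d, survival genes whose probes may not tell the paralogs apart, rose by 1.11 ± 0.09 and 1.10 ± 0.10 in FI-Delta and by 1.79 ± 0.09 and 1.92 ± 0.09 in Y577F cells. The survival gene Mcl1 rose by 1.29 ± 0.11 in Y577F cells. Among genes chosen after their values were seen, the survival gene Bcl2 fell by 0.84 ± 0.13 in FI-Delta cells and by 0.49 ± 0.12 in Y577F cells, the latter a call lost without either Y577F time array. The death-promoting gene Bcl2l11 rose by 1.10 ± 0.09 in Y577F cells and by 0.38 ± 0.09 in FI-Delta cells, the latter a call lost without 0 h array 1, 72 h array 2, FI-Delta time array 2 or Y577F time array 1. Blood transcription factors were not called as a set by camera in FI-Delta (camera adjusted p = 0.12) or Y577F cells (camera adjusted p = 0.15). With fry the set was called in Y577F cells (fry adjusted p = 0.0024) but not in FI-Delta cells (fry adjusted p = 0.073). Id2, an inhibitor of helix-loop-helix factors, rose in both lines (1.54 ± 0.12 and 1.82 ± 0.12, difference 0.28 ± 0.13 with adjusted p = 0.236), and Sox4 fell by 1.51 ± 0.10 in FI-Delta cells. FoxO and growth arrest genes had a median of -0.01 and a mean of 0.14 in FI-Delta cells, and the set was called higher (camera adjusted p = 0.012, and adjusted p = 0.5 with an estimated correlation). In Y577F cells, 11 of 33 rose, led by the growth inhibitor genes Btg1 (1.40 ± 0.09) and Btg2 (1.37 ± 0.10) (camera adjusted p = 0.0036, and adjusted p = 0.36 with an estimated correlation). Without Y577F time array 1, 2 rose and both camera calls were lost, with adjusted p = 0.187 in FI-Delta and 0.183 in Y577F cells.

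Erythroid and megakaryocyte markers were higher as a set in Y577F cells at 0 h (median 0.13, camera adjusted p = 0.001, and adjusted p = 0.12 with an estimated correlation) and at 72 h (median 0.14, camera adjusted p = 0.047, and adjusted p = 0.22 with an estimated correlation). The call at 72 h was lost, with adjusted p between 0.0562 and 0.0804, without FI-Delta time array 1, 72 h array 2, either Y577F time array or 0 h array 3. Over time the set was not called by camera in FI-Delta (camera adjusted p = 0.16) or Y577F cells (camera adjusted p = 0.33). With fry it was called in FI-Delta (fry adjusted p = 0.0065) and Y577F cells (fry adjusted p = 0.0066). Hba-a1 fell by 1.30 ± 0.08 in FI-Delta cells. Lymphoid markers were not called as a set over time in FI-Delta (camera adjusted p = 0.6) or Y577F cells (camera adjusted p = 0.84). Of 23 heat shock and unfolded protein genes, 6 fell in FI-Delta cells, led by the chaperone gene Hyou1 at -0.86 ± 0.11 (camera adjusted p = 3.2e-06, and adjusted p = 0.06 with an estimated correlation). Of 39 proteasome subunits, 11 fell in Y577F cells, and 1 did without Y577F time array 1 (median -0.20, camera adjusted p = 0.00026, and adjusted p = 0.28 with an estimated correlation). Histones had a median of -0.20 in Y577F cells, led by H1f1 at -1.48 ± 0.11 (camera adjusted p = 0.0033, and adjusted p = 0.11 with an estimated correlation). Their medians were -0.414 on Y577F time array 1 and -0.067 on array 2. Of 14 histones 4 fell, and 1 did without Y577F time array 1. Over time in Y577F cells, no shift was called for glycolysis genes (median 0.04, mean -0.02, camera adjusted p = 0.83), oxidative phosphorylation genes (camera adjusted p = 0.83) or ribosomal protein genes (camera adjusted p = 0.38).

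The sum of the 4 sides of the square of comparisons, which would be 0 without noise or culture differences, had a standard deviation of 0.245 over features, against 0.535 if the 4 sides were independent. The standard deviation of single 0 h line arrays was 0.232 to 0.275. The difference of the line arrays correlated with the difference of the time arrays with r = 0.664 over all features.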
